A study of Homo sapiens with 6 samples.

How the data were processed

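HCT116, a human colorectal cancer cell line, was transfected with an siRNA against POU2F1 (siPOU2F1) or with a non-targeting siRNA (sicontrol), and RNA was collected 48 h later, per the labels' protocols. Each group held 3 libraries, prepared from 2 µg of total RNA extracted with TRIzol and made with a directional polyA library kit. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The siRNA sequences are not given in the sources used here.

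The authors deposited 1 table of FPKM values per library (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, StringTie 2.1.2 and the genome build hg38, without saying which step each served. The annotation release, any filter and the strand setting of the counting are not given in the sources used here. Each table listed the same 22782 features, of which 20474 were annotated genes and 2308 were transcripts assembled from the reads, and the assembled transcripts held between 1.18% and 1.30% of the FPKM sum of a library. The comparisons used the annotated genes, and 20460 of their identifiers were found in the reference table of gene names. No 2 libraries held identical values. FPKM values carry no read counts, so absolute depth is unknown. Low values that differed between libraries by 1 common ratio gave relative depths of 1.00, 0.93 and 0.90 for sicontrol replicates 1 to 3 and 0.78, 0.97 and 0.94 for siPOU2F1 replicates 1 to 3, each from a comparison with sicontrol replicate 1 resting on 9 to 18 genes. Compared directly, the log2 depth of siPOU2F1 replicate 1 was -0.26 relative to sicontrol replicate 2 and -0.21 relative to sicontrol replicate 3 (7 and 12 genes). Relative to siPOU2F1 replicate 1, siPOU2F1 replicate 3 had 0.27 (12 genes) but siPOU2F1 replicate 2 had -0.040 (7 genes), so all but the last put siPOU2F1 replicate 1 as the shallower library.

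Values were used as deposited, without further scaling, as log2(FPKM + 0.5). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 11831 genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, group as the only term, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Fold changes are therefore on the log2(FPKM + 0.5) scale, which understates the change of low genes, and each is siPOU2F1 minus sicontrol. For POU2F1 an exact two-sided permutation test of its 6 values was added, which cannot give a p under 0.1 with 3 libraries per group. Gene lists, 37 in number, were fixed before the data were examined, and the 30 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Of the 20 genes in the list of noncoding RNAs, 1 matched an annotated row and the others are not used here.

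The genes named in the text follow a rule fixed before the data were examined. It takes POU2F1 and tested members of its family list, and the 8 called genes with the largest rise and the 8 with the largest fall among those with at least 5 FPKM in the higher group and no overlap between groups. It adds up to 4 members with the lowest p from each of the lists on RNA polymerase III, tRNA processing, tRNA modification, aminoacyl-tRNA synthetases and RNA interference. From every other list called by camera it takes up to 3 members with the lowest p among those moving in the list's direction. A few genes that the rule takes are left out of the text. Genes named outside this rule, among them untested family members, markers of other cell types and genes that overlap a named gene, were chosen after their values were seen.

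Gene positions, overlaps and 3′ UTR sequences came from GENCODE release 29 on GRCh38, the same build as hg38, with 1-based coordinates, using for each gene the transcript with the longest coding sequence in the basic annotation set. After the data were examined, each 7-base word was tested for whether genes holding it in a 3′ UTR of at least 20 bases changed more than others. Fold changes were first regressed on 3′ UTR length, 3′ UTR base composition and transcript GC content, then ranked. The search covered 11520 genes and the 15531 of 16384 words present in at least 100 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

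The procedures were tested on simulated data built from the means and residual variances of this comparison, with 11831 genes, no structure shared between libraries and 200 changed genes in each of 20 runs. The fit recovered 5% of genes changed by 0.5 on the log2 scale, 65.7% of those changed by 1 and 93.9% of those changed by 2, and 5.23% of its calls were false. Camera called a list shifted by -0.3 in 20 of 20 runs, with 2 calls of other lists over all runs. Genes were simulated independently, whereas the correlation estimated within the real lists reached 0.62 (cytosolic ribosomal proteins). These runs therefore do not give camera's rate of false calls on the real lists. The word search, run on 11520 genes with permuted fold changes, ranked a word carrying a shift of -0.1 first in 20 of 20 trials.

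Alternatives fixed before the data were examined were other pseudocounts and filters, median centring, quantile normalization, the fit without a trend or with robust estimation, the replicate number as a block, each library left out in turn, other thresholds and other list tests. Those added after the data were seen were the assembled transcripts included, library weights, removal of GC and length trends, and removal of genes holding 1 of 2 words in the 3′ UTR.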

Results

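Gene expression was measured by polyA RNA sequencing in HCT116 colorectal cancer cells 48 h after transfection with an siRNA against POU2F1, which encodes the octamer-binding transcription factor OCT1, or with a non-targeting siRNA. The comparison asked how the transcriptome of these cells differed once POU2F1 had been lowered, within a study of tRNA-derived fragments. Each group held 3 libraries, and between 11670 and 11853 annotated genes per library had at least 1 FPKM. Mitochondrially encoded genes held 6.53%, 7.55% and 8.42% of the FPKM sum in sicontrol replicates 1 to 3 and 6.45%, 6.05% and 7.73% in siPOU2F1 replicates 1 to 3. The libraries did not separate by siRNA on the main axis of variation. The first principal component held 60.4% of the variance and placed siPOU2F1 replicate 3 on the side of the sicontrol libraries. The second (18.9%) did separate the groups, with sicontrol replicates 1 to 3 at 0.44, 0.04 and 0.46. The siPOU2F1 replicates 1 to 3 lay at -0.07, -0.11 and -0.76 on it. Across genes, siPOU2F1 replicate 3 correlated with siPOU2F1 replicates 1 and 2 at r = 0.946 and r = 0.948, below its correlation of 0.977 with sicontrol replicate 2, whereas siPOU2F1 replicates 1 and 2 correlated with each other at r = 0.989. Genes are not independent replicates, so these correlations describe the libraries and carry no test.

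**Figure D1:**
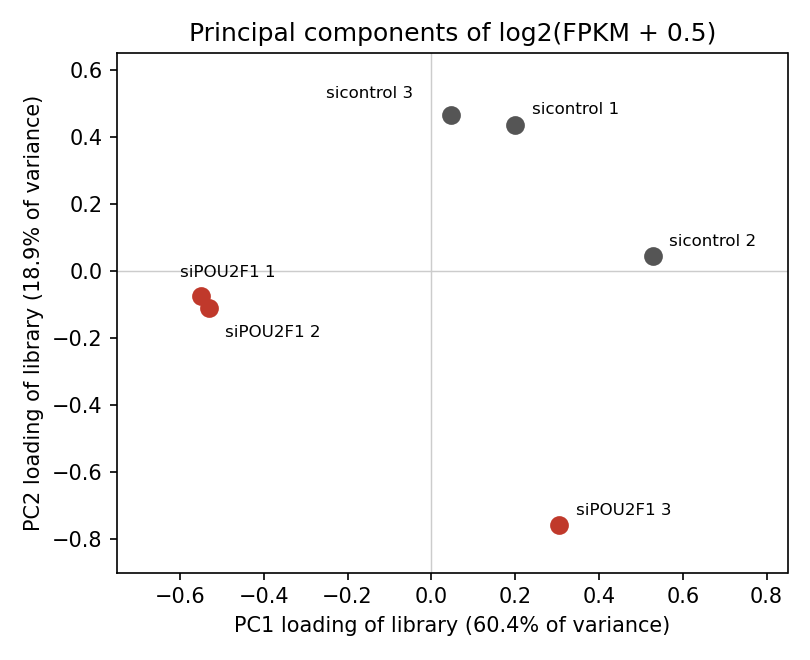
Loadings of the 6 libraries on the first 2 principal components of log2(FPKM + 0.5) over the 11831 tested genes, with sicontrol libraries in grey and siPOU2F1 libraries in red. The first component (x axis, 60.4% of the variance) places siPOU2F1 replicates 1 and 2 opposite the other libraries. The second (y axis, 18.9%) places every sicontrol library above every siPOU2F1 library, with siPOU2F1 replicate 3 at -0.76.

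POU2F1 (ENSG00000143190; chromosome 1, 167220829 to 167427345, plus strand, GRCh38) was lower in every siPOU2F1 library. It measured 4.16, 3.60 and 4.26 FPKM in sicontrol replicates 1 to 3 and 1.87, 1.69 and 1.73 FPKM in siPOU2F1 replicates 1 to 3. The mean fell from 4.01 ± 0.359 to 1.76 ± 0.0984 FPKM (SD, n = 3 each), which is 44.0% of the control level. The log2 fold change was -0.99 with an SE of 0.14 (limma, adjusted p = 0.0333). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. HCFC1, a transcriptional co-regulator in the same list, had a log2 fold change of -0.07 with an SE of 0.26 and was not called (limma, adjusted p = 0.899). Of the other listed family members and cofactors, POU2F2 had means of 0.975 and 0.864 FPKM and POU2AF3 had means of 0.726 and 0.630 FPKM in sicontrol and siPOU2F1, below the level tested, and both are named although they were chosen after their values were seen. Left out 1 at a time, each of the 5 libraries other than siPOU2F1 replicate 3 took the adjusted p of POU2F1 to between 0.114 and 0.222, with log2 fold changes from -1.06 to -0.95 over all such fits.

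In siPOU2F1 cells 47 genes were higher and 100 were lower than in sicontrol cells, among 11831 tested. Of these, 19 rose and 41 fell at least 2-fold. The largest rises were in TPM4, a tropomyosin of actin filaments, from 99.7 ± 19.3 to 347 ± 61.3 FPKM (SD, n = 3 each; log2 fold change 1.79), and in SGK1, a serum- and glucocorticoid-regulated kinase, from 9.91 ± 0.741 to 32.5 ± 3.34 FPKM (1.66). AK6, an adenylate kinase, rose with a log2 fold change of 1.65, PRSS33, a serine protease, with 1.53, ZNF267, a zinc finger gene, with 1.44, and KIF9, a kinesin, with 1.39. GANAB, the catalytic subunit of the endoplasmic reticulum glucosidase that trims N-glycans, rose from 58.7 ± 5.22 to 149 ± 5.39 FPKM (1.34), and TM4SF1, a tetraspan membrane protein, rose by 1.32. AK6 shares 24.5% of its exonic bases with TAF9 on the same strand, whose means were 24.8 and 24.4 FPKM, so the assignment of reads between them is uncertain.

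The largest falls were in ATL3, an atlastin that shapes the tubular endoplasmic reticulum, from 18.3 ± 2.21 to 3.62 ± 1.36 FPKM (SD, n = 3 each; log2 fold change -2.24), and in HINT3, a histidine triad nucleotide-binding protein, from 9.04 ± 1.26 to 1.57 ± 0.168 FPKM (-2.20). FYCO1, an adaptor for autophagosome transport on microtubules, had a log2 fold change of -1.93. JDP2, a repressor related to the AP-1 factors, had -1.88, CPEB4, a cytoplasmic polyadenylation regulator, -1.80, and CDC42, a small GTPase of cell polarity, -1.76. KIF3B, a kinesin motor subunit, had -1.72, and USP25, a deubiquitinase, -1.68. These 16 largest changes had adjusted p from 0.00772 to 0.0486 and SE from 0.10 to 0.27 (limma).

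Many of the genes that fell, though not all, held the same sequence in their 3′ UTRs, which was found after the data had been examined. The word AACTGCA was present in the 3′ UTR of 51 of the 99 searched genes that fell (51.5%), in 0 of the 47 that rose and in 1382 of 11374 that were not called (12.2%). These shares carry no test, since the word was chosen from the fold changes of the same libraries. Among the genes named above, HINT3 and USP25 held 1 copy and JDP2, CPEB4 and KIF3B held 2 copies, whereas ATL3, FYCO1 and CDC42 held none. POU2F1 itself held 2 copies in its 3′ UTR. A further word from the same search, AGAATGA, which ranked 7 for lower expression over all libraries, was present in 35 of the 99 genes that fell (35.4%), in 2 of the 47 that rose and in 14.7% of those not called. Either word was present in 67 of the 99 (67.7%) and in 23.2% of genes not called.

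All 147 called genes had groups that did not overlap, as did 2763 of the 11831 tested genes (23.4%, where chance gives 10%). The count rested strongly on single libraries. It was 2990 without siPOU2F1 replicate 3, and those included all 147, but 0 without sicontrol replicate 1, siPOU2F1 replicate 1 or siPOU2F1 replicate 2, 5 without sicontrol replicate 2 and 9 without sicontrol replicate 3 (limma; 1331, 1261, 1179, 1316 and 2043 genes had an unadjusted p under 0.05 in those fits, in that order, against 2143 with all libraries).

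**Figure D2:**
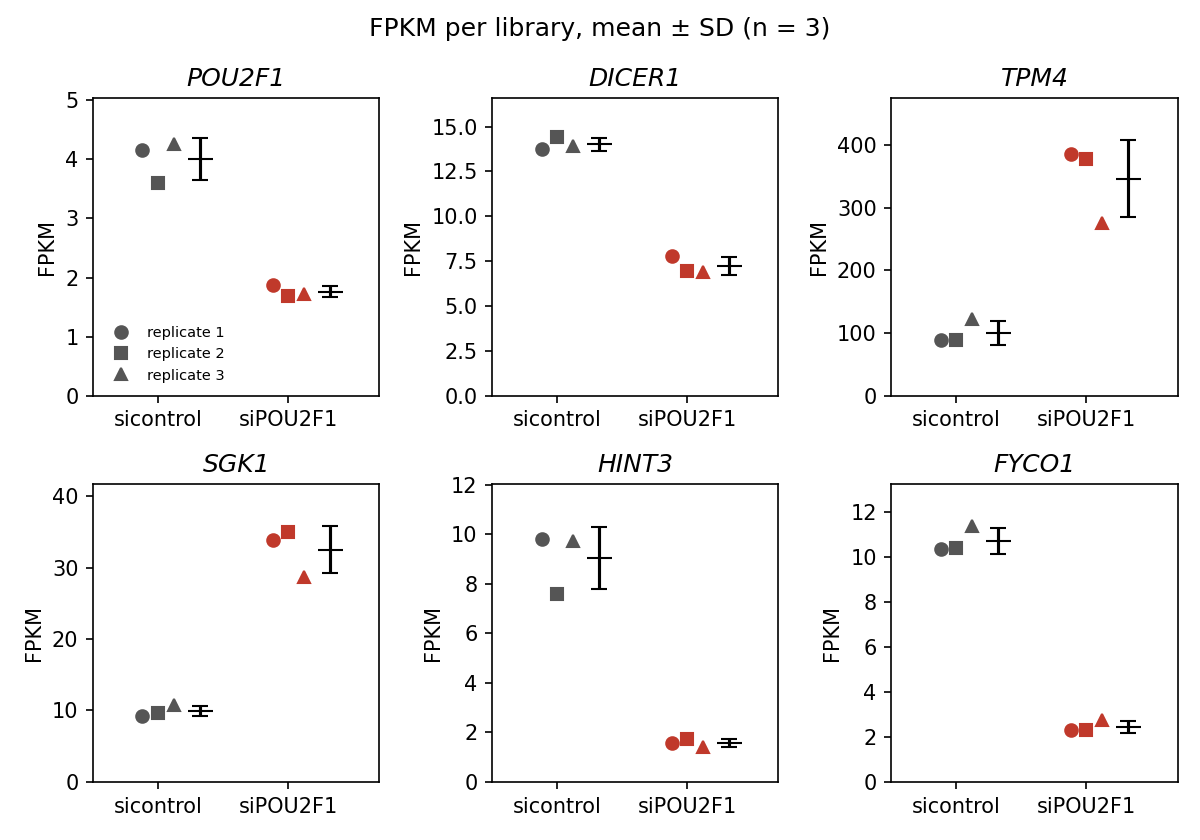
FPKM (y axis) of POU2F1, DICER1, TPM4, SGK1, HINT3 and FYCO1 in each sicontrol (grey) and siPOU2F1 (red) library, with marker shapes for the replicate and bars for the mean ± SD (n = 3). POU2F1 lies between 3.60 and 4.26 FPKM in sicontrol and between 1.69 and 1.87 FPKM in siPOU2F1, and the groups do not overlap for any of the 6 genes.

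Because the study concerns fragments of tRNA, the genes that make, cut and modify tRNA were examined as lists. DICER1, the RNase III that cuts microRNA precursors (ENSG00000100697; chromosome 14, 95086228 to 95158010, minus strand), fell from 14.02 ± 0.361 to 7.21 ± 0.495 FPKM (SD, n = 3 each), a log2 fold change of -0.92 with an SE of 0.11 (limma, adjusted p = 0.0223). It was the only called gene among the 33 tested genes of tRNA processing, cleavage and export, and its adjusted p lay between 0.0934 and 0.169 without any 1 of the 5 libraries other than siPOU2F1 replicate 3. RPP30, a protein subunit of RNase P, had a log2 fold change of -0.83 (adjusted p = 0.0759), XPO5, an exportin of small RNAs, -0.28 (0.288), and ANG, the ribonuclease that cleaves tRNA under stress, 0.66 (0.171). ANG shares 51.0% of its exonic bases with RNASE4 on the same strand, whose means were 1.52 and 3.69 FPKM, so their reads cannot be assigned with certainty. With p adjusted over the list alone, 2 members were lower, and camera did not call the list (adjusted p = 0.254). The DICER1 3′ UTR held AACTGCA at 95087760 to 95087766 and at 95086962 to 95086968 on chromosome 14, both in exon 29 of 29. The same 3′ UTR held AGAATGA at 95087300 to 95087306, and the coding part held AACTGCA in exons 8, 15 and 23.

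Among 54 tested tRNA modification enzymes, TRUB1, a pseudouridine synthase, fell by 1.02 on the log2 scale (adjusted p = 0.0493), from 13.3 ± 0.809 to 6.36 ± 1.55 FPKM (SD, n = 3 each). Without any 1 of the 5 libraries other than siPOU2F1 replicate 3, the adjusted p of TRUB1 lay between 0.127 and 0.268 (limma). The TRUB1 3′ UTR held 1 copy of AGAATGA and 0 of AACTGCA. TRIT1, which adds the isopentenyl group to adenosine, had -0.61 (0.0614), THG1L, the guanylyltransferase of histidine tRNA, -0.52 (0.117), and FTO, an N6-methyladenosine demethylase, 0.50 (0.133), and none of these passed. Adjusted over the list alone, 2 members were lower, and camera did not call this list (adjusted p = 0.931), whose median log2 fold change of -0.07 and mean of -0.09 had the opposite sign to the camera direction. None of 30 genes of RNA polymerase III and its factors was called, whether adjusted over all genes or adjusted over the list alone. Those with the lowest p were POLR3D (-0.45), POLR3GL (0.55), POLR3F (-0.56) and POLR3K (-0.27), with adjusted p from 0.168 to 0.291, and camera gave 0.484 for the list. None of 22 cytosolic aminoacyl-tRNA synthetase genes was called by either adjustment. RARS1 (-0.36), KARS1 (0.32), MARS1 (-0.36) and YARS1 (-0.45) had adjusted p from 0.163 to 0.214, and camera gave 0.0787 for that list. The synthetase list was called lower without siPOU2F1 replicate 3 (0.0188), with library weights (0.0277) and without the genes holding AACTGCA or AGAATGA (0.0271), but had 0.785 with an estimated correlation. Removing those genes also changes what camera compares a list with, and the words had been chosen for lower expression. The synthetase median was -0.24 without them and -0.23 with all genes, so that call adds no separate support. In siPOU2F1 replicates 1 to 3 the list medians were -0.25, -0.27 and 0.14 for tRNA processing, -0.22, -0.05 and 0.22 for tRNA modification, -0.17, -0.22 and 0.08 for RNA polymerase III and -0.31, -0.33 and 0.05 for the synthetases.

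The RNA interference and microRNA machinery was lower as a list (camera adjusted p = 0.00785; median log2 fold change -0.32; 10 of 13 members negative). The adjusted p was 0.684 with an estimated correlation. DICER1 was its 1 called member, and 3 members were lower when adjusted over the list alone. TNRC6A, a scaffold of the silencing complex, had -0.62 (adjusted p = 0.104), AGO2, the slicing Argonaute, -0.49 (0.113), and PRKRA, a partner of DICER1, -0.46 (0.192). The word AACTGCA was present in the 3′ UTR of 6 of the 13. The list medians were -0.35, -0.38 and -0.15 in siPOU2F1 replicates 1 to 3. Without the genes holding AACTGCA or AGAATGA in the 3′ UTR the list was no longer called (camera adjusted p = 0.243), but with fewer members its median was still -0.23.

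Of 30 tested lists camera called 9, of which 4 were higher and 5 lower in siPOU2F1. The same test called up to 16 lists in other splits of the 6 libraries, 3 against 3. Of the 10 splits, the real one included, 6 reached 9 calls, so the number of calls does not set the siRNA apart from other groupings. None of the 9 was called with an estimated correlation, where adjusted p lay between 0.59 and 0.79, and none with fry, which tests whether members move one way on balance. Fry's mixed test, for change in either direction, called 3 of the 9 (NF-kB targets, 0.0384, the interferon response, 0.0405, and RNA interference, 0.00487) and 4 lists that camera did not call (NRF2 targets, glycolysis, apoptosis regulators and mesenchymal genes). Cholesterol synthesis and uptake was higher (adjusted p = 0.000526 with the preset correlation and 0.684 with an estimated correlation), with 24 of 25 members positive and a median log2 fold change of 0.34, but no member was called by either adjustment. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, had 1.74 with an SE of 0.53 (adjusted p = 0.166), and NSDHL had 0.60 (0.156). The median of this list was 0.50, 0.55 and -0.01 in siPOU2F1 replicates 1 to 3, and 0.51 without siPOU2F1 replicate 3. WNT targets and intestinal stem cell genes were higher (0.000947, and 0.59 with an estimated correlation), with 21 of 25 positive, a median of 0.26 and none called by either adjustment. MYC measured 167 ± 0.54 FPKM in sicontrol and 238 ± 35.2 FPKM in siPOU2F1 (SD, n = 3 each; 0.50, adjusted p = 0.113), SP5 had 0.75 and APCDD1 0.62. The list medians were 0.32, 0.38 and 0.17 in siPOU2F1 replicates 1 to 3, and the median was 0.17 without siPOU2F1 replicate 2.

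Nuclear-encoded oxidative phosphorylation genes were higher (camera adjusted p = 0.00529, and 0.785 with an estimated correlation), with 54 of 76 positive and a median of 0.10. Over all genes 1 member was called (limma), and NDUFB6 (0.70) and NDUFA8 (0.56) were not. Adjusted over the list alone, 2 were higher. Cytosolic ribosomal proteins were higher by the same test (0.00529, and 0.785 with an estimated correlation) with a median of 0.10 and none called by either adjustment. RPL15 had 0.21 and RPL37A 0.46. RPS18 had 3.42 with an SE of 1.56, from values between 0.299 and 68.7 FPKM that varied within both groups, and ribosomal protein genes have many processed copies, so their values are uncertain. The ribosomal list was not called after quantile normalization (0.44), nor without sicontrol replicate 2 (0.241), siPOU2F1 replicate 1 (0.115) or siPOU2F1 replicate 2 (0.0691). Its median was 0.045 without sicontrol replicate 2, 0.061 without siPOU2F1 replicate 1, 0.16 without sicontrol replicate 3 and 0.19 without siPOU2F1 replicate 3. The oxidative phosphorylation list was not called without sicontrol replicate 2 (median 0.059, adjusted p = 0.108), and its median was 0.18 without siPOU2F1 replicate 3. In siPOU2F1 replicates 1 to 3 the medians were 0.15, 0.18 and 0.01 for oxidative phosphorylation and 0.19, 0.18 and -0.05 for ribosomal proteins.

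NF-kB targets and inflammatory cytokines were lower (camera adjusted p = 0.000947, and 0.684 with an estimated correlation), with 15 of 19 negative and a median of -0.48. No member was called over all genes, and 8 were lower when adjusted over the list alone. CCL20, a chemokine, measured 31.3 ± 13.7 and 8.04 ± 3.90 FPKM (SD, n = 3 each; -1.91, adjusted p = 0.0714), TRAF1, an adaptor of TNF receptors, had -1.80 (0.0777) and ICAM1, an adhesion molecule, -0.89 (0.0943). The list medians were -0.59, -0.71 and -0.08 in siPOU2F1 replicates 1 to 3. The interferon response was lower (0.00529, and 0.59 with an estimated correlation), with 25 of 34 negative, a median of -0.28, none called over all genes and 5 lower when adjusted over the list alone. OAS3 had -1.02 (adjusted p = 0.0758) and RIGI -0.64 (0.0744). Its medians were -0.27, -0.32 and -0.22, and the list was not called with a filter at 5 FPKM (0.0519).

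The integrated stress response was lower (camera adjusted p = 0.00529, and 0.785 with an estimated correlation), with 28 of 33 negative and a median of -0.36. MTHFD2, a mitochondrial folate enzyme, was the called member by both adjustments and fell from 150 ± 9.74 to 73.6 ± 5.86 FPKM (SD, n = 3 each; -1.02, adjusted p = 0.015). Its 3′ UTR held 1 copy of AACTGCA. Without any 1 of the 5 libraries other than siPOU2F1 replicate 3, the adjusted p of MTHFD2 lay between 0.075 and 0.115 (limma). FGF21 had -1.11 and CBS had -0.36, not called. The list was not called without sicontrol replicate 2 (0.0591), and its medians were -0.53, -0.53 and 0.07 in siPOU2F1 replicates 1 to 3. MTHFD2 shares 29.7% of its exonic bases with SLC4A5 on the opposite strand, whose means were 0.277 and 0.203 FPKM. YAP/TEAD targets were lower (0.0292, and 0.684 with an estimated correlation), with 16 of 20 negative, a median of -0.21, none called over all genes and 3 lower when adjusted over the list alone. NT5E had -1.41, AXL -0.82 and ASAP1 -0.71, and the list medians were -0.34, -0.16 and -0.09. This call was lost without sicontrol replicate 1 (0.0664) or sicontrol replicate 2 (0.0591).

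**Figure D3:**
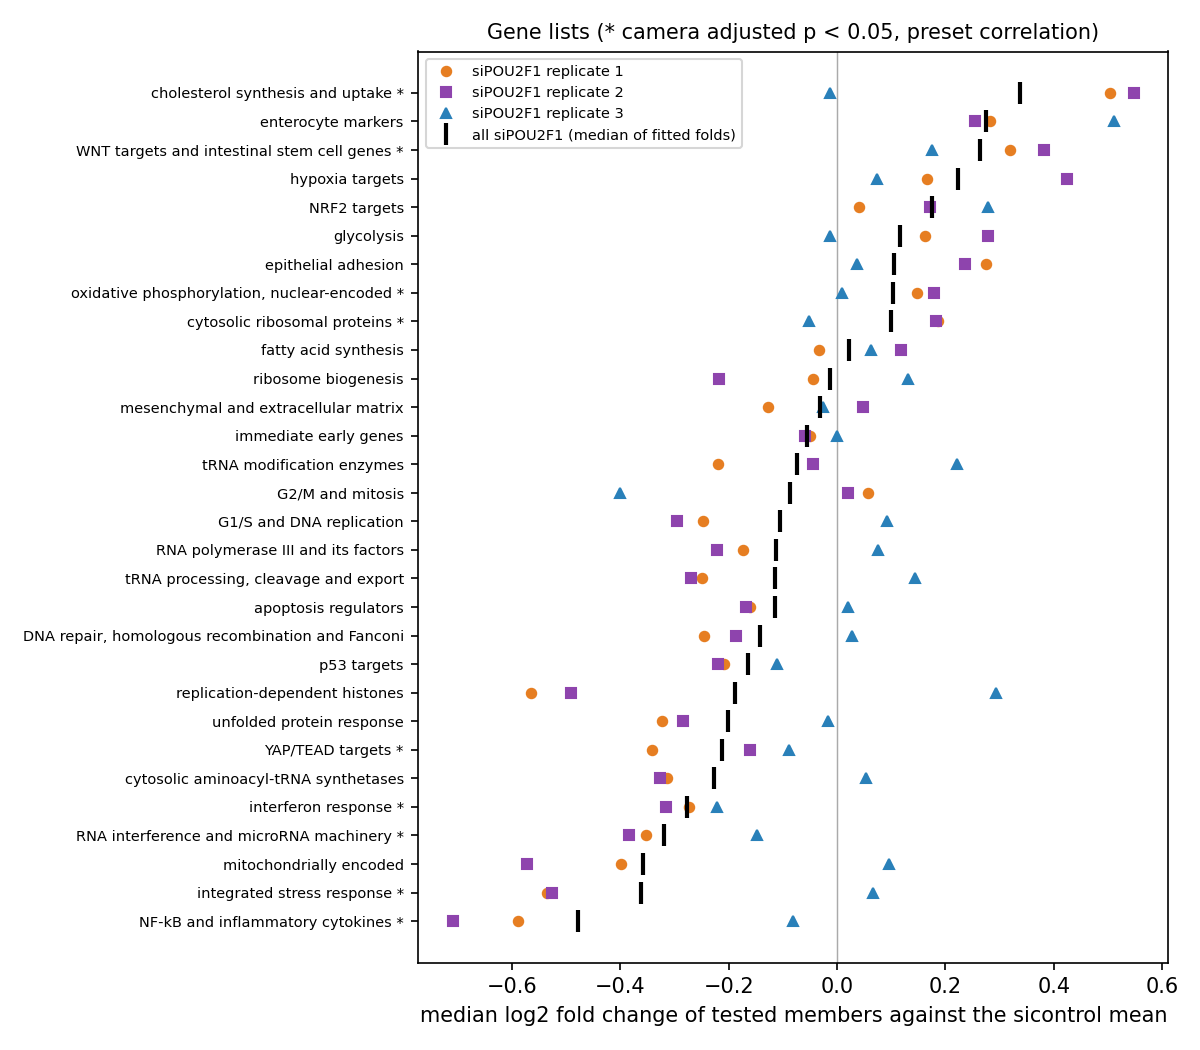
Median log2 fold change of the tested members of 30 gene lists (x axis) in each siPOU2F1 library against the sicontrol mean (coloured markers) and over all siPOU2F1 libraries (black bars), with asterisks on the 9 lists called by camera at the preset correlation. For cholesterol synthesis the medians are 0.50, 0.55 and -0.01 in replicates 1 to 3, and for the integrated stress response they are -0.53, -0.53 and 0.07.

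The other 17 tested lists outside the tRNA topic that camera did not call had adjusted p from 0.0551 to 0.964. Hypoxia targets had a median log2 fold change of 0.22, enterocyte markers 0.27 (5 of 28 genes tested), NRF2 targets 0.18, glycolysis 0.12, epithelial adhesion 0.10 and fatty acid synthesis 0.02. Medians were -0.09 for G2/M and mitosis, -0.20 for the unfolded protein response, -0.16 for p53 targets, -0.14 for DNA repair, -0.11 for G1/S and DNA replication, -0.19 for replication-dependent histones, -0.36 for mitochondrially encoded genes, -0.11 for apoptosis regulators, -0.03 for mesenchymal and matrix genes, -0.05 for immediate early genes and -0.01 for ribosome biogenesis, whose camera direction was opposite to its median and mean. Adjusted over the list alone, 10 members were higher and 16 lower, in 11 of the 17 lists. Members called over all genes are named here in part, although they were chosen after their values were seen. Of the glycolytic genes, LDHA, a lactate dehydrogenase subunit, fell from a mean of 1141 to 443 FPKM (log2 fold change -1.35) and PFKL, a phosphofructokinase, rose (0.76). PLAU, the urokinase, fell (-1.16), as did NDC80 (-0.74) and TMPO (-0.59) of the mitotic list and TXNRD1, a thioredoxin reductase (-0.66). NOLC1, a nucleolar phosphoprotein, rose (1.13).

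Several of these lists passed camera's threshold once 1 library was left out, while leaving out another took some of the same lists towards no change. With an estimated correlation and all libraries, hypoxia targets, glycolysis and G2/M and mitosis each had an adjusted p of 0.785, and none of the 30 lists was called. G2/M and mitosis was called lower without sicontrol replicate 2, siPOU2F1 replicate 1 or siPOU2F1 replicate 2 (adjusted p = 0.00696, 0.000646 and 0.00359), and with all libraries under no filter (0.0469) or without the genes holding AACTGCA or AGAATGA (0.048), but its median was -0.044 (0.284) without sicontrol replicate 3 and 0.020 (0.278) without siPOU2F1 replicate 3. Its medians were 0.06, 0.02 and -0.40 in siPOU2F1 replicates 1 to 3. Without the genes holding either word its median was -0.080, against -0.087 with all genes, so that call adds no separate support. Hypoxia targets were called higher without sicontrol replicate 1, siPOU2F1 replicate 1 or siPOU2F1 replicate 3 (4.98e-05, 0.0446 and 0.0179), and with all libraries by ranks (0.0475), with the replicate block (0.00589) or without the genes holding either word (0.0366). Their median ran from 0.42 without sicontrol replicate 1 to 0.0091 without sicontrol replicate 3 (adjusted p = 0.831), with 0.14 without sicontrol replicate 2 (0.0758) or siPOU2F1 replicate 2 (0.244). Without sicontrol replicate 1 or siPOU2F1 replicate 3, glycolysis was called higher (0.00431 and 0.0216), and DNA repair (0.0373 and 0.0228, medians -0.15 and -0.24) and G1/S and DNA replication (0.0123 and 0.0472, medians -0.19 and -0.23) were called lower. The G1/S median was 0.019 without sicontrol replicate 3 (0.923) and -0.051 without siPOU2F1 replicate 1 (0.34) or siPOU2F1 replicate 2 (0.598). The glycolysis median was 0.18 without sicontrol replicate 1 and 0.20 without siPOU2F1 replicate 3, but 0.075 without sicontrol replicate 2 (adjusted p = 0.133), 0.048 without sicontrol replicate 3 (0.744) and 0.076 without siPOU2F1 replicate 2 (0.317). Mitochondrially encoded genes were called lower without sicontrol replicate 1 (0.0254), but had a median of -0.11 without sicontrol replicate 3 (0.972) and -0.094 without siPOU2F1 replicate 2 (0.598). Without sicontrol replicate 3, p53 targets (0.0394, median -0.26), replication-dependent histones (0.0464, with 22 of 58 genes tested with all libraries) and the unfolded protein response (0.0464) were called lower. The histone median was -0.41 in that fit, but -0.096 without sicontrol replicate 2 (0.852), -0.081 without siPOU2F1 replicate 1 (0.567) and -0.077 without siPOU2F1 replicate 2 (0.456), and it was -0.33 without sicontrol replicate 1 (0.111) and -0.42 without siPOU2F1 replicate 3 (0.0759). NRF2 targets were called higher without siPOU2F1 replicate 1 (0.0446), but had a median of 0.12 without siPOU2F1 replicate 3 (0.298). Enterocyte markers were called higher without siPOU2F1 replicate 2 (0.0353), but 5 of the 28 listed were tested with all libraries, so most of the list was below the level tested.

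Markers of cell types that an HCT116 culture should not hold were few above 1 FPKM, and those named here were chosen from lists fixed earlier after their values were seen. Leukocyte markers CD68 and CD74 had means of 5.42 and 62.7 FPKM in sicontrol and 5.54 and 73.3 FPKM in siPOU2F1. Fibroblast markers COL1A1 and S100A4 had means of 2.198 and 237 FPKM in sicontrol and 2.90 and 289 FPKM in siPOU2F1. Of the kidney and liver line markers, SERPINA1 had means of 242 and 175 FPKM (adjusted p = 0.093), GAL 39.8 and 37.9 FPKM, PAX8 6.36 and 5.72 FPKM and LHX1 2.79 and 2.54 FPKM. Of the goblet and tuft cell markers, IL17RB had means of 5.08 and 5.18 FPKM, PLCG2 1.60 and 2.18 FPKM and PTGS1 1.58 and 1.73 FPKM. TUG1, the matched gene of the noncoding RNA list, had 25.3 and 21.9 FPKM. Of the enteroendocrine markers, SYP, the synaptic vesicle protein synaptophysin, rose from 1.82 ± 0.387 to 5.22 ± 0.728 FPKM (SD, n = 3 each; log2 fold change 1.31, limma, adjusted p = 0.032), while CHGB had 1.32 and 2.53 FPKM (adjusted p = 0.0807). None of the other markers named here was called. Adjusted over the list alone, SYP and CHGB were higher and SERPINA1 was lower.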

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

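The fit that included the assembled transcripts was chosen after the data had been seen. It tested 735 transcripts that were assembled from the reads and carry no annotated gene name, and called 3 of them (limma). The transcript MSTRG.26063.4 was listed at 0 in every sicontrol library and lay between 13.8 and 17.6 FPKM in the siPOU2F1 libraries, with a mean of 16.3 (adjusted p = 0.00015), which is a signal in data outside the annotated genes. MSTRG.27002.4 rose from 1.66 ± 0.186 to 3.78 ± 0.25 FPKM (SD, n = 3 each; limma, adjusted p = 0.0416). In the other direction, MSTRG.26528.1 lay between 2.08 and 2.25 FPKM in sicontrol and was listed at 0 in every siPOU2F1 library (adjusted p = 0.0121). A listed 0 can be a failed estimate, since assembled transcripts share reads with their neighbours, and the positions of these transcripts are not given in the sources used here.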

How the results depend on the processing

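The settings added after the data were seen were the assembled transcripts, library weights, the removal of GC and length trends and the removal of genes with AACTGCA or AGAATGA. Absolute depth is unknown for FPKM values, so no limit from counting error can be given. A count-based test, named among the alternatives fixed earlier, was not run because the values are FPKM, and the filter at 5 FPKM gave no value for POU2F1.

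POU2F1 stayed lower under every alternative with a value. Its call was lost with no filter (-0.99, adjusted p = 0.065), with the replicate block (-0.99, 0.297) and with GC and length trends removed (-0.87, 0.0537), and over the alternatives that kept all libraries its adjusted p ran from 0.000406 to 0.297. Left out 1 at a time, the libraries gave -1.06 to -0.95.

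The number of genes changed was 72 with no filter, 93 without the trend, 49 without the genes holding either word, 60 with a 2-fold limit, 5 at an adjusted p under 0.01 and 0 with the replicate block. It was 5963 with library weights, which gave siPOU2F1 replicate 3 a weight of 0.145, and 0 to 2990 with 1 library left out. The other settings gave 127 to 193. Of the 21 called genes that the naming rule takes, 10 passed without the genes holding either word, in part because such genes were no longer tested, 0 passed with the replicate block and 0 to 21 passed with 1 library left out. The number of lists called was 0 with an estimated correlation, 0 with fry and 6 to 14 with 1 library left out, with 8 to 11 under the other settings. The cause was not tested for these changes, apart from the stricter limits and the smaller sets of genes or libraries.

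Replicate numbers did not pair the libraries. Deviations from the group means correlated across genes at 0.13, -0.54 and -0.51 for numbers 1 to 3, and no library correlated best with its own number. The highest such correlation was 0.64, between sicontrol replicate 2 and siPOU2F1 replicate 3. With the replicate block in the limma fit, 0 genes and 0 of the 21 were called, with 1208 genes at an unadjusted p under 0.05, and 11 lists were called, among them glycolysis (0.048) and hypoxia targets (0.00589). Without the block, camera at the same preset correlation gave 0.0787 for glycolysis and 0.0551 for hypoxia targets. With an estimated correlation and no block, both had 0.785.

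The results whose direction turned were not called with all libraries and the settings of the report, though G2/M and mitosis, mitochondrially encoded genes and histones were called in some other fits. For gene lists the direction is that of camera, which can turn while the median keeps its sign. For tRNA modification enzymes the median was -0.13 with the filter at 5 FPKM, -0.075 with the replicate block and with fry, -0.15 with library weights, -0.047 without the word genes and -0.17 to 0.094 with 1 library left out. For ribosome biogenesis it was -0.0027 after quantile normalization, -0.013 with the replicate block, fry and ranks, -0.067 with weights, -0.0099 without the word genes and -0.13 to 0.032 with 1 library left out. G2/M and mitosis had 0.0093 with weights and -0.20 to 0.020 with 1 library left out. With 1 library left out the values were -0.14 to 0.0031 for immediate early genes, -0.095 to 0.067 for mesenchymal genes and -0.33 to 0.093 for HCFC1. They were -0.47 to -0.094 for mitochondrially encoded genes and -0.42 to -0.077 for histones, where camera's direction turned in 1 such fit each and no median changed sign. Without a turn in camera's direction, the left-out medians ran from 0.050 to 0.25 for epithelial adhesion, 0.0021 to 0.15 for fatty acid synthesis, -0.18 to -0.024 for apoptosis regulators, -0.17 to -0.047 for RNA polymerase III, -0.20 to -0.022 for tRNA processing and -0.23 to 0.019 for G1/S. The cause was not tested.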

Other observations

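The tests of POU2F1 level and mixed cells in siPOU2F1 replicate 3, the ranks of both words, base composition, the DICER1 percentile and the counts of splits were chosen after the results had been seen, and that on GC and length before.

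Lists of histones and of cell-cycle genes had medians that differed between the siPOU2F1 libraries. Replication-dependent histones had list medians of -0.56, -0.49 and 0.29 in siPOU2F1 replicates 1 to 3, and G1/S and DNA replication genes had -0.25, -0.30 and 0.09, whereas G2/M and mitosis genes had 0.06, 0.02 and -0.40. These are single libraries, so the differences carry no test. Of the 58 listed histone genes 22 were tested, in libraries made with a polyA kit. An effect of polyA selection on their values was not tested.

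Further genes passed only when adjusted over the list alone and were chosen after their values were seen. DNAJB11, a chaperone of the endoplasmic reticulum, had means of 84.4 and 42.1 FPKM in sicontrol and siPOU2F1 and a log2 fold change of -1.02 (limma, adjusted p over the list alone of 0.0188). Among p53 targets, TNFRSF10B, a TRAIL receptor, had -0.82 and DDB2, a DNA damage sensor, -0.57 (0.0283 each). Among apoptosis regulators APAF1 had -0.85 (0.0121), and among NF-kB targets CXCL8 had -1.26 (0.0235) and BIRC3 -0.85 (0.014). In the other direction, H2BC21, a histone gene, had 0.88 (0.018), CEACAM1 0.83 (0.0306) and FN1, which encodes fibronectin, 0.61 (0.0192).

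The library siPOU2F1 replicate 3 lay apart from siPOU2F1 replicates 1 and 2. A weaker knockdown is argued against, since the size of the log2 fold of POU2F1 in replicates 1 and 2 (mean) minus that in replicate 3 was -0.032, with values of -0.92, -1.04 and -1.01 in replicates 1 to 3. A large admixture of control cells is argued against too, since the fall of genes with AACTGCA was 0.798 times as large in replicate 3 (95% bootstrap interval 0.647 to 0.997). The bootstrap drew genes, so its interval holds no spread between libraries. Relative to genes without the word, these genes shifted by -0.13 in replicate 3 and by 0.023, 0.015 and -0.036 between sicontrol libraries. GC content and transcript length took 1.8% of the variance of the difference between replicate 3 and replicates 1 and 2. A different state of the culture at collection may be the source, and with 1 such library this stays open. No biological explanation was tested.

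The word AACTGCA came from a search of 15531 words, and a candidate explanation for the genes that fell is off-target silencing through a 7-base seed match of the siRNA. AACTGCA was the lowest word in each of the 3 comparisons of same-numbered libraries, so the word chosen in any 1 of them ranked 1 in the others, which share no library with it (z = -9.92, -8.12 and -12.8 for numbers 1 to 3), whereas between sicontrol libraries its z was -0.02, -0.88 and 0.36. Length and base composition are argued against, since in the comparisons that had not been used to choose the word 0% of 396 reorderings of its bases had a z as low (the lowest had -6.06, -4.80 and -7.28 for numbers 1 to 3). Genes with 1 copy shifted by -0.16 and those with 2 or more by -0.23 relative to genes without. These shifts come from the libraries of the search and were not adjusted for 3′ UTR length or composition, so they carry no test of copy number. POU2F1 holds AACTGCA in its coding part at 167376039 to 167376045 on chromosome 1 (exon 7 of 16), as 11.5% of all 7-base words occur there. The siRNA sequence is not given in the sources used here, and an effect of POU2F1 loss on these genes stays open, as untested.

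DICER1 may have fallen through the 2 AACTGCA sites in its 3′ UTR, since genes with this word fell as a set. DICER1 also held 1 copy of AGAATGA in its 3′ UTR. Its fold change lay at percentile 8.76 among the 217 genes with 2 or more sites, inside the range from 5 to 95 set for this explanation. That range holds most of these genes by construction, and DICER1 is 1 of them, so the percentile lends no support. As a set these genes shifted by -0.23 relative to genes without the word, against a log2 fold change of -0.92 for DICER1. The percentile cannot exclude a response to lower POU2F1 either, and the sources cannot be told apart with 1 siRNA label.

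A related hypothesis, that genes with seed matches of the non-targeting siRNA are released in siPOU2F1 cells, was tested with the word TCGGAGA. This word ranked 1 for higher expression over all libraries (z = 5.03) and was not derived from an siRNA sequence. It was found in 6 of the 47 genes that rose (12.8%) and in 1.77% of genes not called, shares that carry no test. Between sicontrol libraries its z was -0.09, 1.58 and -2.29 (replicates 1 to 3, each against the others). Other words reached a z of up to 6.81 in size in those sicontrol comparisons (TATTTAT, replicate 1). The size of the z of TCGGAGA therefore does not set it apart from words that differ without a change of siRNA. The same holds for AGAATGA, with a z of -5.79 over all libraries. The outcome turned on how libraries were paired. Either pairing reuses the libraries in which TCGGAGA had been found, so its ranks are not independent of that choice. In the pairing tried first, chosen after the principal components had been seen, TCGGAGA ranked 1 and 4 for higher expression, and AACTGCA ranked 1 in both comparisons for lower. With same-numbered libraries, which replaced it, TCGGAGA ranked 9, 115 and 1 (z = 3.74, 2.46 and 5.67), and 115 lies past the bound of 100 first set against the hypothesis. A demand that z also be at or under 0 was added after that rank was seen, so the hypothesis is not supported here and may only be called open.

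The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 147 genes, the highest of the others called 0, and 1 of the 10 reached the real count. For gene lists the real split called 9, the highest of the others called 16, and 6 of the 10 reached the real count. The split of sicontrol replicates 1 and 2 with siPOU2F1 replicate 3 against the rest gave 3692 genes at an unadjusted p under 0.05, above the 2143 of the real split, though 0 passed adjustment (limma), which points to a structure of the samples other than the siRNA.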
